A study of Homo sapiens with 12 samples.

How the data were processed

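H3K27ac, the acetylated histone mark of active promoters and enhancers, was profiled by CUT&RUN in RPMI 8226, an established multiple myeloma cell line. Cells carried either a scramble control or a knockout of CEBPB, and each was given DMSO vehicle or 10 µM dexamethasone for 2 h. The 4 groups had 3 libraries each, 12 in all. Per the labels, each assay used 100000 cells and a commercial CUT&RUN kit, the reads were aligned to hg38 with Bowtie2 2.4.2, and peaks were called with MACS3 3.0. The labels named no control library for the peak calling. They did not state whether the knockout cells were a clone or a pool, nor whether the 3 libraries of a group came from separate cultures.

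The deposited files were 12 lists of broad peaks, 1 per library. The deposited peak start and end are 0-based positions, a unit recorded as other. The deposited score is 10 times the negative log10 q-value, which held in at least 99.96% of the peaks of each library. Signal in the deposited lists is a ratio, the fold enrichment of a peak over its background. The deposited lists also give a neg_log10_p column, that is −log10 p, and beside it −log10 q. The lowest −log10 q of a library was between 0.523 and 0.535. The lists hold no read counts, so the sequencing depth of each library is unknown and no counting interval could be given.

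Peaks on chromosomes 1 to 22 and X were used; 213 to 296 peaks per library lay on other sequences. For each of 19970 protein-coding genes of the RefSeq gene table, the base pairs covered by peaks were summed from 25 kb before to 25 kb after the gene. The gene table gave no strand, so the window surrounded the gene's whole span where the design had named the transcription start site; the narrower and wider windows of 5 and 100 kb, and the 1 kb around gene ends in the share of peaks at gene ends, departed from the design likewise. Long genes therefore had long windows, and neighbouring windows could overlap, so genes were not independent. The 17152 genes with any covered base in at least 3 libraries were tested. Values were log2(base pairs + 500), quantile-normalised over the 12 libraries. Differences were tested with limma 3.58.1 (trend and robust empirical Bayes, 8 residual degrees of freedom) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The contrasts were dexamethasone in each genotype, knockout under each treatment, the difference between the drug responses (interaction), and the averages of the drug and knockout effects.

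The named genes followed a rule. Up to 10 genes higher and 10 lower were taken per contrast by the largest log2 difference among those with an adjusted p under 0.05 whose groups did not overlap, which was not asked of the interaction. Of genes whose windows overlapped by over 50%, 1 was kept. Where fewer than 5 passed in a direction, the 5 of smallest p were taken and are said not to have passed. CEBPB and NR3C1 were always included, as were up to 3 members of smallest p per gene list and contrast. The design named genes of an averaged contrast only where a single contrast had no call, and none were taken by size for the averaged knockout effect. Genes of the averaged drug effect were named although both its single contrasts had calls, a departure from the design. Genes outside the rule are named where a list had 5 or fewer calls.

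The 14 gene lists, the tests, the named-gene rule and most alternatives were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 14 lists within a contrast, with an estimated correlation and fry beside it. Members were also counted by p-values adjusted over the list alone.

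Chromosomes 1 to 22 and X were divided into bins of 500 bp, present in a library when at least 250 bp were covered. A gained bin was present in every library of the first group and in none of the second, and a lost bin the reverse. Adjoining bins were merged into runs and given their nearest gene. Peak number, covered length, median width, the share of peaks at gene ends and covered length in strong peaks were compared by exact two-sided permutation tests, as were shares of covered length per chromosome. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used.

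The gene test was tested on simulated data in which 200 genes were changed in 1 comparison. It recovered 61% of those changed by log2 1 and 92% of those changed by log2 2, with 10 false calls in that comparison and 0 in an unchanged one. The simulated genes were independent, with normal noise of the same spread in every group. Real windows overlap and some groups are listed at 0 throughout, so these rates need not hold for the real data. The bin code gave exact results in 50 of 50 simulated interval sets and found 200 of 200 planted bins.

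Alternatives were windows of 5 and 100 kb, covered length trimmed to 48.0 Mb in every library, only peaks with −log10 q of at least 5, an offset of 100 bp, no normalization, scaling to the library total, no gene filter, a filter of 6 libraries, a replicate block, a fit of only the contrast's groups, limma without trend and robust options, all chromosomes and scaffolds, other bin sizes and rules, and leaving out each library. Windows of 5 and 25 kb around the 2 gene ends, and the tests without genes of 4 chromosomes, were added after seeing the data. Motif and GC content tests of the bins, with their alternatives, were not run because a genome sequence was not used here.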

Results

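The data are 12 lists of H3K27ac peaks from RPMI 8226 multiple myeloma cells, with 3 libraries in each of 4 groups. Scramble control cells and cells with a knockout of CEBPB, the gene of the transcription factor C/EBPβ, were treated with DMSO or with dexamethasone, a synthetic glucocorticoid. According to its title, the series asks how loss of C/EBPβ affects enhancer responses to the drug. Each library held 41164 to 56421 peaks on chromosomes 1 to 22 and X, which covered 48.0 to 66.4 Mb. Read depth is unknown because the lists hold no counts. Nothing in the labels states that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between libraries.

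No difference between groups in the covered length was detected. Peaks covered 58.9 ± 6.8 Mb (mean ± SD, n = 3) in scramble cells with DMSO, 52.7 ± 6.2 Mb with dexamethasone, 58.2 ± 5.5 Mb in knockout cells with DMSO and 54.4 ± 4.0 Mb with dexamethasone. The drug difference of −5.00 Mb gave p = 0.155 and the knockout difference of 0.516 Mb gave p = 0.84 in exact two-sided permutation tests stratified by the other factor. Of the 5 measures tested for both factors, only peak width had an unadjusted p under 0.05, with medians of 1013 ± 15 bp in knockout and 984 ± 21 bp in scramble libraries (exact permutation p = 0.015, 6 libraries each, not adjusted for the 10 tests). The fraction of shared bins of 500 bp (Jaccard index, bins present in both libraries over bins present in either) was 0.558 ± 0.031 in 12 pairs of libraries of 1 group. It was 0.549 ± 0.022 in 18 pairs that differed in treatment and 0.485 ± 0.019 in 18 pairs that differed in genotype.

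In scramble cells, dexamethasone raised H3K27ac coverage at 4 genes. By log2 size the first was ZBTB16, a known glucocorticoid target that encodes a zinc finger repressor (hg38 chromosome 11, 114059711 to 114256770). Its window held 0.646 ± 0.65 kb of peaks with DMSO and 12.1 ± 2.3 kb with dexamethasone (log2 difference 3.80 ± 0.36 SE, n = 3, adjusted p = 0.0017). The neighbouring NNMT, which encodes nicotinamide N-methyltransferase (114257806 to 114313536), rose from 0.112 ± 0.19 to 2.62 ± 0.58 kb (log2 2.64 ± 0.23, adjusted p = 0.00085). The windows of ZBTB16 and NNMT overlap, so these calls are not independent. TNFSF8, the gene of CD30 ligand (chromosome 9, 114893343 to 114930595), is listed at 0 in the 3 DMSO libraries and held 2.21 ± 0.14 kb with the drug (adjusted p = 6.1e-06). TRIM40, a tripartite motif gene on chromosome 6 (30136140 to 30148735), rose from 0.104 ± 0.18 to 2.38 ± 1.1 kb (adjusted p = 0.0029). Whether these peaks lie in exons or introns was not examined.

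**Figure D1:**
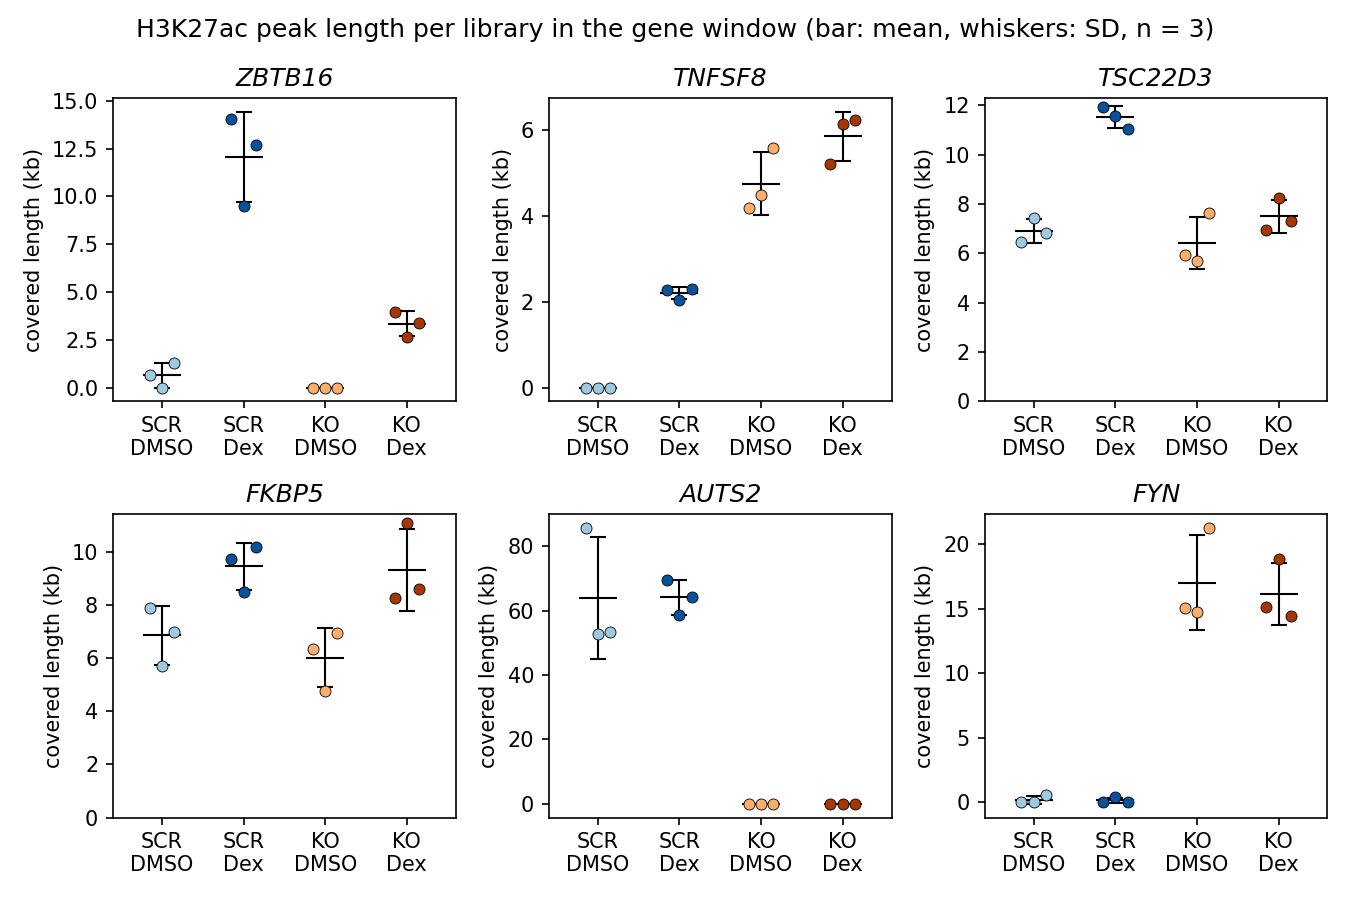
Kilobases covered by H3K27ac peaks in the gene windows of ZBTB16, TNFSF8, TSC22D3, FKBP5, AUTS2 and FYN (y axis) in the 4 groups (x axis). Points are libraries, bars are means and whiskers are SD (n = 3). ZBTB16 averages 12.1 kb in scramble cells with dexamethasone and 3.34 kb in knockout cells with dexamethasone. Its drug response (log2 3.80 and 2.93) was not called different between the genotypes.

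In the fit of all 12 libraries with 25 kb windows, no gene fell with dexamethasone in scramble cells. The 5 lower genes of smallest p did not pass: CHST2 was covered over 1.36 ± 0.23 kb with DMSO and is listed at 0 with the drug (adjusted p = 0.057), and PLD1, PTPN3, ACADS and RNF213 had log2 differences of −1.40, −0.99, −1.29 and −0.72. Lower calls appeared under other settings, 15 beside 63 higher with strong peaks alone, 4 beside 7 without a gene filter and 3 each with 100 kb windows, equal covered length and the 100 bp offset. PTPN3 passed with 5 kb windows (log2 −1.04), equal covered length (−1.12) and the offset (−1.29), PLD1 with 100 kb windows (−1.50) and the offset (−2.06), and CHST2 without a gene filter and in limma without trend and robust options. Leaving out scramble DMSO library 3 (PLD1, −1.62), knockout DMSO library 1 (CHST2, adjusted p = 0.018) or knockout DMSO library 2 (CHST2, adjusted p = 0.026, and RNF213, log2 −0.72) also made them pass. Of the 17152 genes tested with limma, 1314 had an unadjusted p under 0.05, where 857.6 would be expected by chance. Groups did not overlap at 2014 genes (11.7%, against 10% by chance). The 4 calls were made without any 1 of the 12 libraries, but the number of calls grew and took in lower genes. It was 10 without scramble DMSO library 1 (8 higher and 2 lower) or 2 (6 and 4), 11 without scramble dexamethasone library 1 (5 and 6), 8 without its library 3 (6 and 2), and 9 (7 and 2) and 7 (5 and 2) without knockout DMSO libraries 1 and 2. When only strong peaks were counted, TNFSF8 (log2 0.34) and TRIM40 (log2 0.25) were no longer called, and ZBTB16 and NNMT had strong peaks in too few libraries to be tested. TRIM40 was also not called with windows of 5 kb (log2 0.42) or 100 kb (log2 0.49) or without normalization (log2 2.23), and both ZBTB16 (log2 3.74) and TRIM40 (log2 2.39) missed the threshold when only the 6 scramble libraries were fitted. Around gene ends with 5 kb, TNFSF8 (log2 0.81) and TRIM40 (log2 0.35) did not pass, a window chosen after seeing the data.

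Glucocorticoid-induced genes rose as a group in scramble cells. Of the 45 tested members, 35 had higher and 10 lower coverage, with a median log2 difference of 0.19 (camera adjusted p = 3.8e-05, and adjusted p = 0.070 with an estimated correlation). The direction count alone does not set the list apart. Housekeeping genes had 19 higher and 5 lower and the BCL2 family 13 and 2, with smaller medians (0.056 and 0.071). Cell cycle genes (12 and 13) and NF-κB and inflammatory genes (13 and 15) were even. One member, ZBTB16, passed over all genes and 4 passed when adjusted over the list alone. The other 3 were TSC22D3, FKBP5 and PDK4. TSC22D3, which encodes the glucocorticoid-induced leucine zipper GILZ (chromosome X, 107713221 to 107775988), was covered over 6.90 ± 0.49 kb with DMSO and 11.5 ± 0.45 kb with the drug (log2 0.80, adjusted p = 0.069 over all genes). TSC22D3 passed over all genes with 100 kb windows (log2 0.75), strong peaks alone (1.33), the 100 bp offset (0.84), no gene filter (0.80) and without scramble DMSO library 2 (0.89). FKBP5, which encodes a chaperone of the glucocorticoid receptor (chromosome 6, 35573590 to 35728583), was covered over 6.85 ± 1.1 and 9.45 ± 0.87 kb (log2 0.53, adjusted p = 0.28). NR3C1, the gene of the glucocorticoid receptor itself (chromosome 5, 143277931 to 143435512), differed by log2 −0.10 (adjusted p = 0.92), and that sign turned with equal covered length or strong peaks.

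The other 13 lists did not pass camera with dexamethasone in scramble cells, and 0 of their members were called over all genes by limma. Adjusted over the list alone, the list of NF-κB and inflammatory genes (29 tested) had 1 higher member, REL, and 3 lower ones, TNF, LTB and LTA. REL encodes a subunit of NF-κB and differed by log2 0.71 (adjusted p = 0.20 over all genes). TNF and LTB, adjacent cytokine genes with equal window values, differed by −0.70, and the neighbouring LTA by −0.44, so these 3 are not independent. IKZF1, a lymphoid transcription factor that myeloma cells depend on, was the only plasma cell and myeloma gene of 29 to pass over the list alone (log2 −0.57, adjusted p = 0.23 over all genes). No member passed over the list alone among the C/EBP family (7 tested), genes linked to C/EBPβ (21), the BCL2 family (15), the unfolded protein response (23), immediate early and AP-1 genes (20), the cell cycle (25), housekeeping genes (24) or markers of T cells (14), myeloid cells (15), mature B cells (15) and stromal or epithelial cells (11).

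In knockout cells, dexamethasone raised coverage at 3 genes. ZBTB16 is listed at 0 in the knockout DMSO libraries and held 3.34 ± 0.65 kb with dexamethasone (adjusted p = 0.023). PHACTR3, which encodes a regulator of protein phosphatase 1 and actin (chromosome 20, 59577509 to 59847711), rose from 1.66 ± 0.68 to 8.23 ± 1.3 kb (log2 2.12 ± 0.20, n = 3, adjusted p = 0.0068). Its coverage was also higher with the drug in scramble cells, at 6.20 ± 0.39 and 13.3 ± 2.2 kb, without being called there. ADGB, the androglobin gene (chromosome 6, 146598972 to 146815462), is listed at 0 in the other 3 groups and held 1.25 ± 0.26 kb in knockout cells with dexamethasone (adjusted p = 0.023). MAST4 and RAB21 were next and did not pass, with log2 differences of 0.66 and 0.93 (adjusted p = 0.071 for both). RAB21 passed with 5 kb windows (log2 0.90), scaling to the library total (0.97), no gene filter (0.93) and limma without trend and robust options (0.93), and MAST4 with 100 kb windows (0.58). No gene fell with limma; the 5 of smallest p, CPLX1, CD44, RBFA, MAPK8IP1 and CYP2D6, had log2 differences of −0.97, −1.66, −0.75, −1.09 and −1.78. With strong peaks alone 49 genes were lower and 56 higher, with 100 kb windows 6 and 9, and at equal covered length 2 and 8. CD44, a cell adhesion receptor gene, passed at equal covered length (log2 −1.66), in limma without trend and robust options and without knockout dexamethasone library 3 (−1.95), and CYP2D6 without knockout dexamethasone library 2 (−2.23).

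With limma, 1091 genes had an unadjusted p under 0.05 for dexamethasone in knockout cells, and groups did not overlap at 2096 genes (12.2%, against 10% by chance). These 3 calls were fragile. Without knockout DMSO library 3, 0 genes were called (PHACTR3 adjusted p = 0.057), and without knockout dexamethasone library 1, 0 genes were called as well (PHACTR3 adjusted p = 0.074). ZBTB16 passed only without scramble DMSO library 2 or 3, and its adjusted p without 1 of the other 10 libraries reached 0.16. It was also lost with the 100 bp offset, no normalization, no gene filter and around gene ends with 5 or 25 kb. ADGB passed in none of the 9 fits without 1 library that tested it. The count was 1 without scramble DMSO library 1 or any of scramble dexamethasone libraries 1 to 3. PHACTR3 was not called with strong peaks alone (log2 1.70), and neither PHACTR3 (2.12) nor ADGB (1.75) when only the 6 knockout libraries were fitted. With windows of 25 kb around gene ends, an alternative added after seeing the data, 0 genes were called.

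Glucocorticoid-induced genes also rose as a group in knockout cells, with 31 members higher and 14 lower and a median log2 difference of 0.12 (camera adjusted p = 0.00071, and adjusted p = 0.15 with an estimated correlation). By direction alone the BCL2 family was similar (10 higher and 5 lower), and housekeeping genes were more even (13 and 11). Without knockout DMSO library 1 the list gave an adjusted p of 0.055. ZBTB16 passed over all genes, and FKBP5, DDIT4 and CXCR4 joined it when adjusted over the list alone. FKBP5 was covered over 6.01 ± 1.1 kb with DMSO and 9.31 ± 1.5 kb with the drug (log2 0.70, adjusted p = 0.23 over all genes). DDIT4, an inhibitor of mTORC1 signalling, differed by log2 0.62 and CXCR4, a chemokine receptor gene, by 0.59. Among NF-κB and inflammatory genes, REL (log2 0.91) and NFKB1 (0.66) passed over the list alone. The remaining 12 lists had 0 members passing by limma over all genes or over the list alone, and none passed camera.

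The drug responses of the genotypes differed at 2 genes in the interaction test. TNFSF8 held 4.75 ± 0.74 kb in knockout cells with DMSO and 5.86 ± 0.57 kb with dexamethasone, against 0 and 2.21 kb in scramble cells. Its response was lower in the knockout by log2 −2.15 ± 0.18 (adjusted p = 0.0017), where the locus was already covered without the drug. NNMT, which is listed at 0 in all 6 knockout libraries, differed by log2 −2.64 ± 0.32 (adjusted p = 0.031). ZBTB16 was not among the 2 calls, with drug responses of log2 3.80 in scramble and 2.93 in knockout cells. TSC22D3 had a difference of −0.48 (adjusted p = 0.82), from 6.42 ± 1.1 to 7.51 ± 0.67 kb in knockout cells. CEBPB and NR3C1 differed by 0.16 and 0.30 and did not pass. Neither did PLD1, ADGB, RNF213, CRLS1 and PTPN3, with log2 differences of 1.86, 1.80, 0.99, 1.59 and 1.16, nor COL23A1, C6orf132 and HNRNPAB, with −1.13, −2.00 and −0.998.

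With limma, 909 genes had an unadjusted interaction p under 0.05. The TNFSF8 call held without any 1 library but ended around gene ends with 5 kb (log2 −0.24), and its direction turned with strong peaks alone (1.36). The NNMT call held only without scramble dexamethasone library 1: leaving out any of the other 11 libraries ended it, with an adjusted p of up to 0.25. It also ended with a 100 kb window (log2 −0.58), and the adjusted p missed the threshold at log2 −4.59 with the 100 bp offset, −2.38 without normalization and −2.48 with scaling to the library total. ADGB passed at equal covered length (log2 1.78), without a gene filter (1.80) and in limma without trend and robust options (1.80), and PTPN3 at equal covered length (1.30). No list passed camera for the interaction, and the glucocorticoid-induced list had 21 members higher and 24 lower (adjusted p = 0.99). IKZF1 alone passed when adjusted over its list, with a log2 difference of 0.75. Across the 17152 genes the log2 responses of the genotypes had a Pearson r of 0.157 and a Spearman rho of 0.117, with the same sign at 54.9%. Across the 45 glucocorticoid-induced genes these values were 0.81, 0.40 and 68.9%. The responses of ZBTB16 (3.80 and 2.93) lay far above the list medians (0.19 and 0.12), and 1 such gene can raise a Pearson r. Genes are not independent replicates.

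Averaged over the genotypes in the fit of all 12 libraries with 25 kb windows, dexamethasone raised coverage at 7 genes and lowered it at 0, with 1489 genes at an unadjusted p under 0.05 by limma. ZBTB16 (log2 3.37), TRIM40 (1.96), PHACTR3 (1.63), TNFSF8 (1.46), NNMT (1.32), TRIM31 (1.16) and REL (0.81 ± 0.10, adjusted p = 0.017) made up the calls. The windows of TRIM31 and TRIM40 overlap, as do those of ZBTB16 and NNMT, so the 7 calls are not 7 separate regions. REL (chromosome 2, 60881574 to 60931612) went from 1.47 ± 0.13 to 2.44 ± 0.27 kb in scramble cells and from 1.10 ± 0.11 to 2.43 ± 0.39 kb in knockout cells. Of the lower genes, CHST2, CLDN20, HPCA, CSTF1 and ZNF234 had the smallest p and did not pass; HPCA, which encodes hippocalcin, differed by log2 −1.67 (adjusted p = 0.13). CHST2 passed with scaling to the library total and in limma without trend and robust options, and CLDN20 in the latter (log2 −1.02). Under other settings 36 genes were lower beside 80 higher with strong peaks alone, and 10 beside 26 with 100 kb windows. The glucocorticoid-induced list rose here too (camera adjusted p = 1.2e-06, and adjusted p = 0.033 with an estimated correlation), and 8 of its genes passed over the list alone, among them SESN1 (log2 0.67) and TXNIP (0.31). AURKA, a mitotic kinase gene, was the only cell cycle gene to pass over the list alone (log2 −0.66, adjusted p = 0.16 over all genes).

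ZBTB16, TRIM40, PHACTR3 and TNFSF8 were called in the average without any 1 library. TRIM31 was called only without knockout DMSO library 2 or 3; without 1 of the other 10 libraries its adjusted p reached 0.17. It was also lost with windows of 5 kb (log2 0.74) or 100 kb (0.34), equal covered length (1.56), the 100 bp offset, no normalization, no gene filter and the filter of 6 libraries. REL was lost without scramble DMSO library 3, scramble dexamethasone libraries 2 and 3, knockout DMSO libraries 2 and 3 or knockout dexamethasone libraries 1 and 2 (adjusted p of up to 0.084), and with windows of 5 kb (log2 0.12) or 100 kb (0.47) or strong peaks alone (0.07). NNMT was lost without scramble DMSO library 3, scramble dexamethasone library 2 or 3 or knockout dexamethasone library 1 (adjusted p of up to 0.084), with the 100 bp offset and without normalization. Around gene ends, PHACTR3 was lost with 25 kb (0.97) and TNFSF8 with 5 kb (0.69). TRIM40 was not called with windows of 5 kb (log2 0.32) or 100 kb (0.50). The count was 16 without scramble DMSO library 1 (10 higher and 6 lower), 11 without its library 2 or knockout DMSO library 1, and 4 without scramble DMSO library 3, scramble dexamethasone library 2 or knockout dexamethasone library 1.

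Single regions changed with dexamethasone at known glucocorticoid target loci. In both genotypes, 73 bins of 500 bp were present in all 6 dexamethasone libraries and in no DMSO library, in 61 runs, and 15 bins showed the reverse. The longest gained run spanned 2.5 kb within ANKRD28, an ankyrin repeat gene (chromosome 3, 15794501 to 15797000). A run of 1.5 kb lay 2.10 kb from PER1, a circadian clock gene induced by glucocorticoids (chromosome 17, 8154501 to 8156000). Runs of 1 kb lay between genes nearest to IGSF21, ETV3 and RGS1. Gained runs were also found at ZBTB16, FKBP5, TSC22D3, CXCR4, REL, SESN1, SESN2 and TRIM40, genes singled out after their values were seen. Gene spans held 27 of the 61 gained runs (44.3%).

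**Figure D2:**
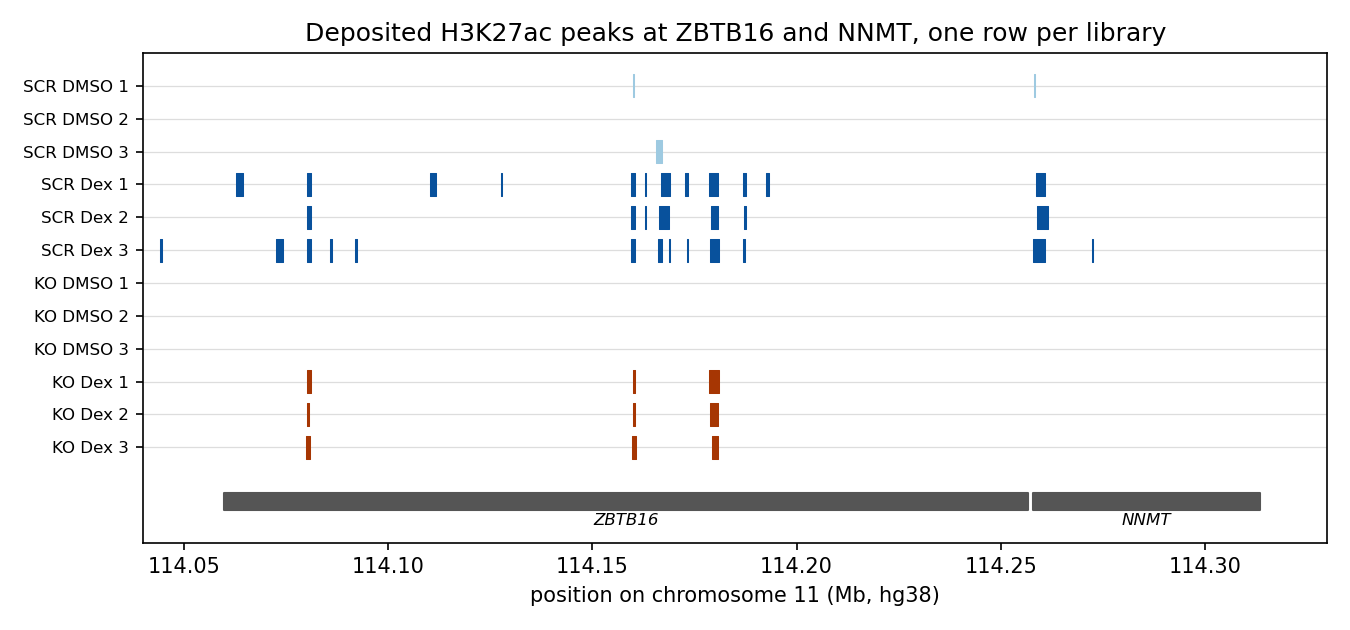
H3K27ac peaks of the 12 libraries (1 line each, coloured by group) along a stretch of chromosome 11 (x axis, Mb, hg38), with the spans of ZBTB16 and NNMT. Peaks in the ZBTB16 window cover 12.1 kb on average in the 3 scramble libraries with dexamethasone and cover 3.34 kb on average in the knockout libraries with dexamethasone. The drug response of ZBTB16 was not called different between the genotypes.

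Within scramble cells, 1009 bins were gained and 1242 lost with dexamethasone (0.458% and 0.564% of the 220076 bins present in any of these libraries), and within knockout cells 996 were gained and 1330 lost. The lean depended on the setting: at equal covered length 696 were lost in scramble and 779 in knockout cells, and with strong peaks alone 670 were gained and 312 lost in scramble cells and 567 and 615 in knockout cells. The longest gained run in scramble cells, besides ANKRD28, was 2.5 kb within RREB1 (chromosome 6, 7138501 to 7141000), and the longest lost run was 2.5 kb nearest to AGPS. In knockout cells the longest gained run was 3 kb within SMAP2 (chromosome 1, 40389501 to 40392500). Of the 1009 bins gained in scramble cells, 279 were absent from all 6 knockout libraries (27.7%) and 111 were present in all of them (11.0%). More knockout libraries with dexamethasone than with DMSO held 349 of these bins, and fewer did at 165. Another split of the 6 scramble libraries gave 2057 gained plus lost bins, against 2251 in the real one. Many of the 1009 bins may therefore reflect spread between libraries. No share for other bins was computed, so these shares do not measure dependence on C/EBPβ. Without 1 library the counts for scramble cells ranged from 1558 to 2876 gained and from 1947 to 4785 lost bins, since 2 libraries of a group then sufficed.

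The CEBPB locus itself carried H3K27ac in both genotypes. Its window (chromosome 20, 50190583 to 50192690) held 5.61 ± 0.50 kb in scramble and 4.77 ± 0.47 kb in knockout cells with DMSO (log2 −0.25, adjusted p = 0.37), and 4.45 ± 0.31 and 4.43 ± 0.41 kb with dexamethasone (log2 −0.08, adjusted p = 0.82). H3K27ac at a locus does not check whether its protein was lost, and the lists hold no other measure of the knockout. With 100 kb windows CEBPB was called lower in the knockout averaged over treatments (log2 −0.44, adjusted p = 0.0078, against −0.17 and adjusted p = 0.32 with 25 kb); over its other alternatives with all libraries the adjusted p ranged from 0.15 to 0.85. CEBPB lies on chromosome 20, where covered length was lower in the knockout. NR3C1 was covered over 8.56 ± 2.8 kb in scramble and 6.35 ± 0.47 kb in knockout cells with DMSO (log2 −0.43, adjusted p = 0.16).

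Knockout and scramble cells differed at many genes. With DMSO, 648 genes had higher and 608 lower coverage in the knockout; with dexamethasone, 729 were higher and 579 lower. The largest loss was at AUTS2, a neuronal developmental gene (chromosome 7, 69598475 to 70793506), covered over 63.9 ± 19 kb in scramble cells with DMSO and listed at 0 in all 6 knockout libraries (adjusted p = 7.1e-11). The adjacent GALNT17, a glycosyltransferase gene, went from 31.7 ± 7.4 kb to 0. FAT1, which encodes an atypical cadherin (chromosome 4, 186587794 to 186726696), fell from 33.2 ± 4.2 to 0.24 ± 0.21 kb (log2 −5.52 ± 0.21, n = 3, adjusted p = 1.4e-08). CDH4, UNC5C, ADAMTS2, ARHGAP42, EDIL3, DOCK5 and GABRG3 were covered over 12.8 to 21.4 kb in scramble cells with DMSO and are listed at 0 in the knockout with DMSO. With dexamethasone the same genes were named except ADAMTS2, with DOCK1 in its place (16.7 ± 3.6 to 0.122 ± 0.21 kb).

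The largest gain in the knockout was at FYN, which encodes a SRC family kinase (chromosome 6, 111660332 to 111873452). Its window held 0.174 ± 0.30 kb in scramble and 17 ± 3.7 kb in knockout cells with DMSO (log2 4.74 ± 0.31, n = 3, adjusted p = 1.9e-06), and 0.133 ± 0.23 and 16.1 ± 2.4 kb with dexamethasone. GREB1L (chromosome 18, 21242232 to 21526112) rose from 0.789 ± 1.1 to 15.7 ± 2.7 kb, SMOC2, an extracellular matrix gene, from 0.564 ± 0.45 to 14.0 ± 1.2 kb and CACNB2, a calcium channel subunit gene, from 1.15 ± 1.6 to 15.7 ± 4.3 kb. TMC1 rose from 0.160 ± 0.28 to 8.96 ± 1.3 kb. GPR15LG, ACP3, SOBP, CNTN1 and CT45A1 are listed at 0 in all scramble libraries and held 11.8, 8.78, 8.25, 6.52 and 5.40 kb in knockout cells with DMSO. PRICKLE2 was named with dexamethasone, at 0.103 ± 0.18 and 8.08 ± 1.3 kb.

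With limma, 3408 genes with DMSO and 3457 with dexamethasone had an unadjusted p under 0.05, and groups did not overlap at 3846 (22.4%) and 4331 genes (25.3%), against 10% by chance. Between the treatments, which share no library, 397 higher and 368 lower calls were shared, where 27.5 and 20.5 would be expected from independent lists, and 0 had opposite directions. The knockout effects with DMSO and dexamethasone had a Pearson r of 0.749 and a Spearman rho of 0.540 across genes, which are not independent replicates. Every named gene above was called without any 1 library. With strong peaks alone, TMC1 (log2 1.18), CNTN1 (0.51), CT45A1 (1.52), UNC5C (−0.09) and DOCK5 (−0.65) were not called with DMSO, TMC1 (0.56) and UNC5C (−1.49) were not called with dexamethasone, and FYN had strong peaks in too few libraries to be tested. CT45A1 was not called with a 5 kb window (log2 1.37). Around gene ends, chosen after seeing the data, CDH4 (−1.41), TMC1 (1.81) and CT45A1 (1.37) were not called with 5 kb, and CNTN1 (1.14), GABRG3 (−0.80) and, with dexamethasone, PRICKLE2 (0.26) were not called with 25 kb.

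Inflammatory cytokine genes were among the list members that changed in the knockout. Of 29 NF-κB and inflammatory genes, 3 rose and 2 fell with DMSO, the same numbers when adjusted over the list alone, and 6 rose and 1 fell with dexamethasone (6 and 2 over the list alone). CCL3, a macrophage chemokine gene, rose from 0.0967 ± 0.17 to 3.02 ± 0.26 kb with DMSO (log2 2.65 ± 0.20, adjusted p = 6.1e-06), and the adjacent CCL4 by log2 1.67. IL1B is listed at 0 in scramble cells with DMSO and held 1.81 ± 1.5 kb in the knockout (adjusted p = 0.0045). NFKB1 fell by 1.05 on the log2 scale (adjusted p = 0.0023) and CD83, an activation marker, fell by 0.98. With dexamethasone TNF and LTB were higher by log2 0.67 and LTA by 0.49. TNF and LTB have equal window values and LTA neighbours them, and CCL3 adjoins CCL4. The members counted for this list are therefore not all separate loci. As a set the list did not pass camera (adjusted p = 0.61 with DMSO and 0.23 with dexamethasone). By fry it was called higher under each treatment (adjusted p = 0.0021 and 0.00039).

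Single genes of cell survival and plasma cell identity were called, and neither list passed camera. BCL2, which encodes an inhibitor of apoptosis (chromosome 18, 63123346 to 63320090), rose from 16.5 ± 0.71 to 28.3 ± 2.4 kb with DMSO (log2 0.84 ± 0.11, adjusted p = 0.00048) and by log2 0.90 with dexamethasone. Among all genes of chromosome 18, the median log2 difference between knockout and scramble was 0.31. BCL2L11, which encodes the proapoptotic protein BIM and which dexamethasone is known to induce, fell by 0.75 on the log2 scale with DMSO (adjusted p = 0.0076). In the BCL2 family, 1 member rose and 1 fell with DMSO (2 and 1 over the list alone, with BBC3 added), and 1 rose with dexamethasone. Of 21 genes linked to C/EBPβ, 2 rose under each treatment, BCL2 and IL1B. Of 29 plasma cell and myeloma genes, 3 rose and 0 fell under each treatment; CREB3L2 (log2 0.56) and ITGB7 (0.37) passed under both, TNFRSF17, the gene of BCMA, with DMSO (0.52), and IKZF1 with dexamethasone (0.53). Of the glucocorticoid-induced genes, 2 fell with DMSO, BCL2L11 and MT2A (log2 −1.26), and 3 fell with dexamethasone, ZBTB16 (−1.77, adjusted p = 0.010), TLE1 (−1.62) and TSC22D3 (−0.63). Adjusted over the list alone, 4 and 3 of them fell.

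In the unfolded protein response list, ERN1 (log2 0.38) and SEL1L (0.58) rose and DNAJB9 (−0.74), MANF (−0.61) and ASNS (−0.53) fell with DMSO, and 0 of 23 passed with dexamethasone by limma. These single calls were not set against the coverage shifts of long stretches and chromosomes described below. A regional shift is therefore not separated from a change at the gene. IER3 was the only immediate early gene of 20 to pass (log2 0.56 with DMSO). Of the C/EBP family and the cell cycle list, 0 members passed under either treatment, and of housekeeping genes only YWHAZ passed over all genes, with dexamethasone (log2 0.39). Markers of other cell types moved singly. CD2, a T cell surface gene, is listed at 0 in scramble cells with DMSO and held 1.05 ± 0.67 kb in the knockout (adjusted p = 0.016); it passed with dexamethasone too. CD28 rose (log2 0.42) and CD14, a monocyte marker, fell by 0.86 with DMSO. HLA-DRA fell from 1.08 ± 0.19 to 0.204 ± 0.18 kb with DMSO, the only mature B cell marker of 15 to pass, under each treatment. VIM, the vimentin gene, rose from 1.5 ± 0.78 to 5.46 ± 0.20 kb (log2 1.61, adjusted p = 0.0072) and ACTA2 by log2 0.73, the only stromal or epithelial markers to pass over all genes. No list passed camera for the knockout. With fry, the NF-κB and inflammatory list passed under each treatment. With dexamethasone, fry also called plasma cell and myeloma genes (adjusted p = 0.039) and genes linked to C/EBPβ (0.045) higher. It called glucocorticoid-induced genes lower there (adjusted p = 0.039). In the average over treatments these lists passed fry too, with mature B cell markers lower and stromal or epithelial markers higher (adjusted p = 0.034 for both).

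In bins, 4941 were gained and 5382 lost in the knockout with DMSO, and 5654 were gained and 5426 lost with dexamethasone. Under both treatments 1908 bins were present in all 6 knockout libraries and in no scramble library, and 2606 showed the reverse. The longest gained runs with DMSO were a pair of 4 kb within SMOC2 (chromosome 6, 168597501 to 168601500 and 168605501 to 168609500). A run of 4 kb was gained within GREB1L with dexamethasone (chromosome 18, 21262501 to 21266500). The longest lost runs were 4.5 kb nearest to TMTC1 with DMSO (chromosome 12, 30057001 to 30061500) and 5.5 kb within ANKRD30A with dexamethasone (chromosome 10, 37141501 to 37147000). A run of 3.5 kb within RYR2, a calcium release channel gene, was lost under each treatment (chromosome 1, 237184001 to 237187500).

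Several differences extended over long stretches. No knockout library had a peak from 69494386 to 71752229 on chromosome 7, 2.26 Mb that hold AUTS2 and GALNT17, where scramble libraries covered 102 ± 18 kb (SD, n = 6). Stretches without a knockout peak also lay at RBFOX1 on chromosome 16 (6777804 to 7926598), at FAT1 on chromosome 4 (186261344 to 186749740) and at SOX4 on chromosome 6 (21438758 to 22180361). In the other direction, no scramble library had a peak at MCC on chromosome 5 (113075410 to 113294393) or around FYN on chromosome 6 (111606673 to 111872983), where knockout libraries covered 17.3 ± 2.3 and 15.8 ± 2.8 kb. Stretches that held at least 10 kb of peaks in the other genotype numbered 45 without a knockout peak and 5 without a scramble peak. These stretches were examined after the gene results were seen.

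The differences leaned by chromosome. Chromosome 18 took 2.43 ± 0.05% of the covered length in knockout and 1.97 ± 0.04% in scramble libraries (SD, n = 6), and chromosome 2 took 8.40 ± 0.10% and 7.27 ± 0.10%. Chromosome 7 took 4.98 ± 0.03% and 5.86 ± 0.18%, and chromosome 20 took 2.64 ± 0.02% and 3.10 ± 0.03%. In an exact two-sided permutation test within treatments, 18 of 23 chromosomes had an adjusted p under 0.05, 9 higher and 9 lower (smallest adjusted p = 0.0088, from the smallest p of 0.005 that 400 arrangements allow). With strong peaks alone the knockout shares differed from scramble by 15.2% on chromosome 18, 8.80% on chromosome 2, −8.75% on chromosome 7 and −6.79% on chromosome 20, against 23.4%, 15.6%, −15.0% and −14.9% with all peaks. On chromosome 2 the higher coverage lay between 0 and 90 Mb, where 9 of 9 windows of 10 Mb were higher in the knockout, with a median log2 ratio of 0.42, against 0.02 over the rest. Averaged over treatments, 73 genes were called higher and 11 lower on chromosome 18, 184 and 55 on chromosome 2, 35 and 131 on chromosome 7, and 12 and 73 on chromosome 20. Without the genes of these 4 chromosomes, 1936 of the remaining 14521 genes were called. The chromosome tests were chosen after seeing the data.

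**Figure D3:**
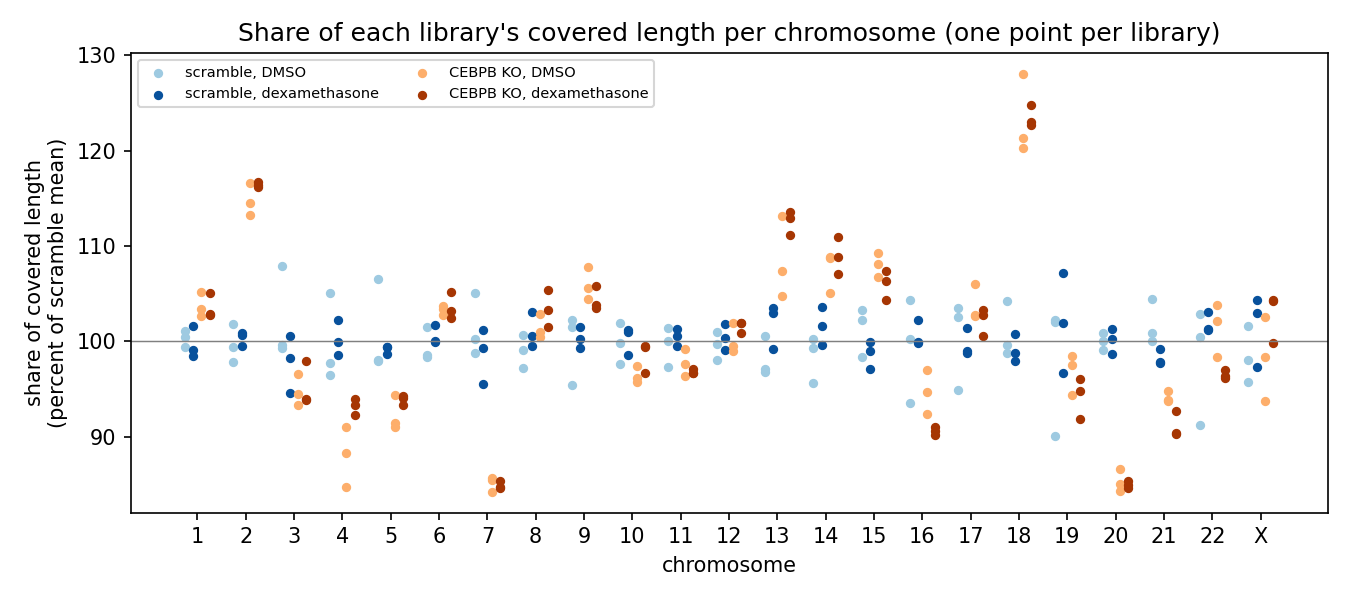
Share of the covered length on each chromosome (x axis) as a percent of the mean scramble share (y axis), with 1 point per library coloured by the 4 groups. Knockout libraries average 23.4% above scramble on chromosome 18 and 15.6% above on chromosome 2, or 15.2% and 8.80% with strong peaks alone.

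**Figure D4:**
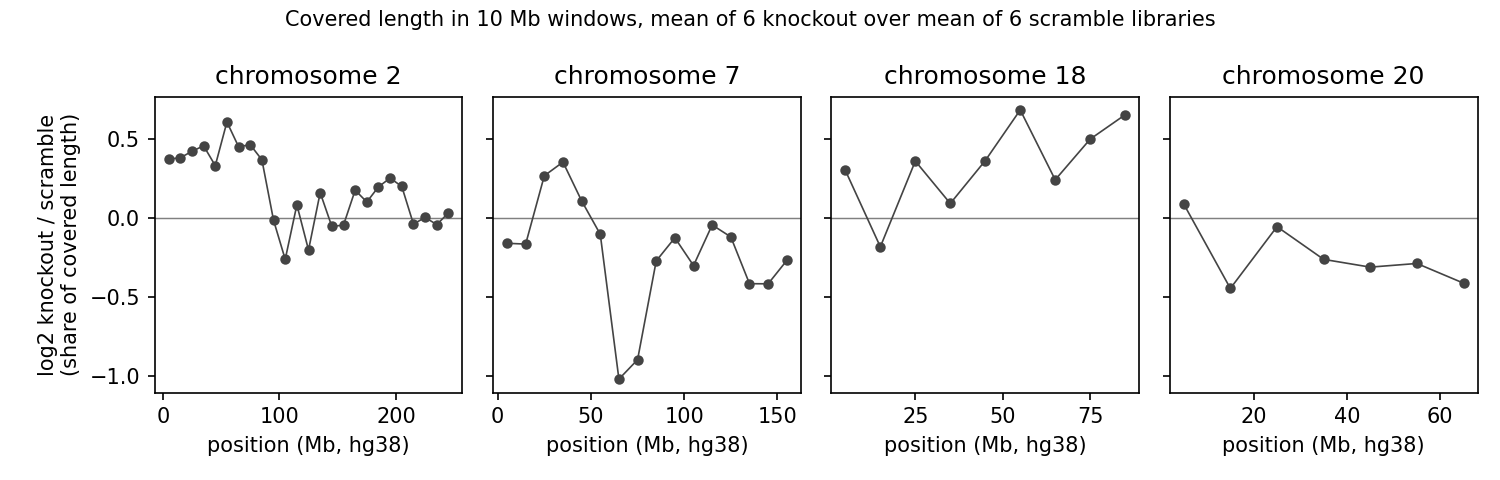
Log2 ratio of the mean share of covered length in knockout over scramble libraries (y axis, 6 libraries each) in 10 Mb windows along chromosomes 2, 7, 18 and 20 (x axis, Mb). On chromosome 2 the 9 windows from 0 to 90 Mb lie between 0.33 and 0.61.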

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

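The tests chosen only after the result was seen were the regroupings of libraries for bins in the 4 pair comparisons, the test of uncalled genes on chromosomes 2, 7, 18 and 20, and the test at TNFSF8 with strong peaks alone.

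The response to dexamethasone differed between the genotypes at TNFSF8 and NNMT in the interaction test, which set them apart. The knockout response was lower by log2 −2.15 at TNFSF8 and by log2 −2.64 at NNMT. In 7 of 100 regroupings of the 12 libraries within strata, the real one included, at least as many genes were called for the interaction, with 2 in the real grouping and 7 in the highest other, so chance is not excluded for this count.

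At TNFSF8, peaks stood in knockout cells without the drug and in scramble cells only with it. A difference in the amount called per library would shrink the interaction at equal covered length, but it stayed at −2.03 (adjusted p = 0.0209), which argues against it. A lower copy number of the locus in the knockout would lower its neighbours, whose median log2 difference was 0.0976 instead. A covered length that cannot register a rise where peaks already stand remains a candidate explanation, since with strong peaks alone the value turned to 1.36 (adjusted p = 0.082). A smaller response of the locus in knockout cells cannot be separated from this without read counts.

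Knockout and scramble libraries differed at many genes in both treatments. A difference in the amount called per library would remove most calls at equal covered length, but 76.2% of the calls were kept, which argues against it. Tested genes 0.2 to 2 Mb from the genes called lower had a median log2 difference of −0.0580, and those near genes called higher 0.0510. These are far smaller than the medians of the called genes (−0.82 and 0.75). Called genes thus did not in general share a shift of their own size with genes at that distance. On chromosomes 2, 7, 18 and 20 these neighbours were at −0.210 and 0.197. Because they moved by so little even there, where coverage leaned by chromosome, the test cannot decide on copy number of chromosome segments. This holds for copy number as a general cause and at single stretches. The part of the calls that copy number could explain stays open. Uncalled genes shifted with the calls on chromosomes 18 (0.146, 95% interval 0.099 to 0.246), 2 (0.082, 0.044 to 0.117) and 7 (−0.087, −0.153 to −0.028). On chromosome 20 (−0.090) the interval includes 0 (−0.189 to 0.033). Outside these 4, every 10 Mb window of chromosome 3 from 0 to 60 Mb was lower in the knockout (log2 ratio −0.29 to −0.54). The labels give 0 batches, so separate handling or culture history of the 2 cell populations cannot be told apart from loss of C/EBPβ, which stays among the open explanations.

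Bins present in every dexamethasone library and in no DMSO library outnumbered the reverse, at 73 against 15. The planned test of a difference in the amount called per library decides nothing. Dexamethasone libraries covered less than DMSO libraries (53.5 ± 4.7 against 58.5 ± 5.5 Mb). Trimming to equal covered length would thus be bound to favour gained bins, and the ratio of 7.45 it gave carries no weight. Before trimming, a larger amount called with DMSO would favour bins present only there, but the excess ran the other way. The drug difference in covered length stayed negative without any 1 library (−6.75 to −3.12 Mb). The untrimmed values argue against a difference in the amount called as the cause of this excess. In 100 regroupings of drug and vehicle within each genotype, only the real 1 gave as many separating bins, 88 against 24 in the highest other. Of 100 regroupings of all 12 libraries, 3 gave as many, the real one included; the highest, with 4514, is the split by genotype, a structure of the samples. A response to the drug common to both genotypes is one hypothesis that these tests leave standing, and it was found and tested on the same data.

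For genes in the 4 pair comparisons, 6 libraries make only 10 regroupings, too few for a share under 5%. Dexamethasone in scramble cells called 4 genes, and 3 of the 10 regroupings called as many, the highest other 12. In knockout cells it called 3, and 3 of 10 called as many, the highest other 4. The knockout called 1256 genes with DMSO, where the highest other grouping called 2, and 1308 with dexamethasone, where the highest other called 1; in each only 1 of 10, the real one, called as many. The same holds for bins: 2251 against 2057 in the highest other for dexamethasone in scramble cells, 2326 against 1940 in knockout cells, 10323 against 1954 for the knockout with DMSO and 11080 against 1381 with dexamethasone. For the averaged knockout effect 1 of 100 regroupings, the real one, called as many as its 2582 genes (highest other 49). A chance division of these libraries is thus unlikely. Regrouping libraries cannot tell whether the 2 cell populations differed by chance. For the averaged dexamethasone effect 1 of 100, the real one, called as many as its 7 genes, but the highest other called 6, a narrow margin beside the 4 to 16 calls found without 1 library. For bins of the knockout in both treatments 1 of 100 gave as many as 4514, the highest other 101.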

How the results depend on the processing

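The alternatives added after seeing the data were the windows of 5 and 25 kb around gene ends and the tests without genes of 4 chromosomes; all others were planned. Of the values of named genes under settings that keep all libraries, 1197 kept their direction and side of the threshold, 69 fell short of it, 28 newly passed and 36 turned direction. The planned windows around transcription start sites were replaced by windows around gene spans because no strand was given, and the motif and GC tests with their alternatives (unmatched background bins, and the 500 bp bin alone) were not run. Depth is unknown, so its effect was not assessed. Fitting only the groups of the contrast moved no count of genes by over 1.5 times, and adding other chromosomes and scaffolds, run for the library totals alone, changed none of their signs. Without normalization the median log2 difference of all genes went from 0.031 to −0.087 for dexamethasone in scramble cells and from 0.024 to −0.081 in the drug average, a shift against which changes without normalization should be read; in the other contrasts it moved by less than 0.1. Where a value below differs, the cause was not tested unless fewer genes or libraries were used. Main values stand in the report.

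With 5 kb windows, 8 genes were called for dexamethasone in scramble and 6 in knockout cells; the CEBPB differences were 0.12 and 0.010 for the drug in scramble and knockout cells, 0.066 for its average, 0.016 for the knockout with DMSO and −0.11 for the interaction, COL23A1 had an interaction of 0.45 and CSTF1 an average of 0.041. With 100 kb windows the counts were 13 and 15 for the drug, 36 for its average, 2433 and 2572 for the knockout with DMSO and dexamethasone and 4699 for its average; RBFA was at 0.038 and CHST2 at 0.031, and CEBPB was called lower in the knockout average (−0.44). Around gene ends with 5 kb, the counts were 15 and 15 for the drug in scramble and knockout cells, 20 for its average, 445 and 537 for the knockout, 946 for its average and 4 for the interaction; RNF213 was at 0.067, RBFA 0.025, COL23A1 0.00092, CSTF1 0.064, and CEBPB at 0.042 for the drug in scramble cells, 0.0058 for the knockout, −0.052 for the interaction and 0.017 for the drug average. Around gene ends with 25 kb, 0 genes were called for the drug in knockout cells, and NR3C1 was at −0.39 there and −0.55 in the drug average.

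At equal covered length, 15 genes were called for the drug in scramble cells, 10 in knockout cells, 22 in the average and 6 for the interaction; RNF213 was at 0.058 for the drug and −0.015 for the interaction, NR3C1 at 0.032, CEBPB in knockout cells at 0.010 and CSTF1 at 0.020, and lost bins numbered 696 in scramble and 779 in knockout cells. With strong peaks alone the counts were 78 and 105 for the drug, 116 for its average and 48 for the interaction, in fits with many very small variances; RNF213 was at 0.011, NR3C1 0.29, CPLX1 0.053, RBFA 0.038, CEBPB in knockout cells 0.035, CSTF1 0.034, and the interactions of PTPN3, TNFSF8, COL23A1 and HNRNPAB at −0.63, 1.36, 0.022 and 0.021. Gained and lost bins were then 670 and 312 for the drug in scramble cells, 567 and 615 in knockout cells, 3207 and 2233 for the knockout with DMSO and 3408 and 3135 with dexamethasone; 3 were lost with the drug in both genotypes and 1329 with the knockout in both treatments, and peak number differed by 231 between knockout and scramble.

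With an offset of 100 bp, 10 genes were called for the drug in scramble cells and 1 for the interaction. The interaction also had 1 call without normalization, with scaling to the library total and with a filter of 6 libraries. Without normalization NR3C1 was at −0.054 in the drug average. Scaling to the library total gave 11 calls in the drug average and CEBPB at 0.00082 for the drug in knockout cells. Without a gene filter the counts were 11 and 6 for the drug, 19 for its average and 7 for the interaction. Without trend and robust options, limma called 7 and 7 genes for the drug and 19 in its average. Without the genes of 4 chromosomes, 4 were called in the drug average. With an estimated correlation the glucocorticoid-induced list gave an adjusted p of 0.070 in scramble and 0.15 in knockout cells, and 1 list was called over the 7 contrasts; fry called 14.

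A replicate block gave 1 call for the interaction, where NNMT was lost (adjusted p = 0.21); it also ended the calls of ADGB in knockout cells (0.15) and of NNMT, TRIM31 and REL in the drug average (0.052, 0.073 and 0.064), and HPCA newly passed there (0.045). Residuals of the 18 pairs of libraries with the same number had correlations from −0.0793 to 0.0954, and 0 exceeded 0.1, so the numbers do not pair the libraries and the block is no better than the fit without it.

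With 1 kb bins, gained and lost bins were 470 and 591 for the drug in scramble cells, 473 and 587 in knockout cells, 2262 and 2453 for the knockout with DMSO, 2769 and 2427 with dexamethasone and 891 and 1192 in both treatments, and 30 were gained with the drug in both genotypes. Requiring all 500 bp gave 621 and 710, 810 lost in knockout cells, 2954 and 2915, 3499 and 2918, 998 and 1271 in both treatments, and 38 and 8 for the drug in both genotypes. Counting any covered base gave 2010 lost for the drug in scramble cells, 8338 and 8258 lost for the knockout with DMSO and dexamethasone, 114 and 25 for the drug in both genotypes and 2943 and 4220 for the knockout in both treatments. Asking only for a difference of 2 of 3 libraries gave 7946 and 12729 for the drug in scramble cells, 8221 and 12306 in knockout cells, 983 and 1657 in both, and 19788 and 18685 for the knockout with DMSO, 19401 and 17117 with dexamethasone and 9200 and 8748 in both treatments.

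Leaving out each library in turn, the counts of genes ranged from 4 to 11 for the drug in scramble cells, 0 to 3 in knockout cells, 4 to 16 in the average and 1 to 2 for the interaction, and the glucocorticoid-induced list in knockout cells had adjusted p from 0.00011 to 0.055. Fewer libraries per group made the bin rule easier to meet: gained and lost bins ranged from 1558 to 2876 and 1947 to 4785 for the drug in scramble cells, 1521 to 2744 and 2176 to 4556 in knockout cells, 6069 to 8833 and 6166 to 9763 for the knockout with DMSO, and 6728 to 9146 and 6312 to 9182 with dexamethasone, and 27 to 61 were lost with the drug in both genotypes. The knockout difference ranged from −2138 to 747 peaks and from −1.05 to 2.4 Mb. CEBPB ranged from −0.056 to 0.044 for the drug in knockout cells, and NR3C1 from −0.24 to 0.089 for the drug in scramble cells and from −0.024 to 0.14 in its average.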

Other observations

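The tests of the list near gained bins and of the AUTS2 stretch were chosen after the results were seen.

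Averaged over the treatments, 1389 genes had higher and 1193 lower H3K27ac coverage in the knockout, with 4666 at an unadjusted p under 0.05 by limma. Of the pair comparisons and this average, several list members passed over all genes only in the average; CD40 and TNIP1 were picked after their values were seen. CD8A, a T cell gene, rose by log2 0.91 (adjusted p = 0.011) and CD40, a B cell activation receptor gene, by 0.64 (adjusted p = 0.048). BACH2, a B cell transcription factor gene, fell by 0.42 (adjusted p = 0.026), MAFF by 0.32 (adjusted p = 0.042) and TNIP1, an inhibitor of NF-κB signalling, by 0.32 (adjusted p = 0.021). BBC3, which encodes the proapoptotic PUMA, rose by 0.32 (adjusted p = 0.032). CRISPLD2, a glucocorticoid-induced gene, fell by 1.31 (adjusted p = 0.0064). Shifts of coverage over long stretches or chromosomes were not separated from these calls. In 6 against 6 libraries, the T cell markers did not move together: CD3D and CD3E had log2 differences of −0.47 and −0.88 and did not pass over all genes, but were lower when adjusted over the list alone.

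Long runs of bins separated the genotypes in both treatments within CYRIA on chromosome 2 and MCC on chromosome 5, which were gained in the knockout over 3 kb each. EDIL3, an extracellular matrix gene, had a lost run of 3.5 kb (chromosome 5, 84382001 to 84385500). Genes called for the knockout were longer than the others, with median spans of 50.3 and 24.9 kb, and longer genes had longer windows. Of the bins that scramble cells lost with dexamethasone, 292 of 1242 were absent from all knockout libraries (23.5%) and 116 were present in all of them (9.34%). No share for other bins was computed beside these.

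A hypothesis is that the bins gained with dexamethasone in both genotypes mark glucocorticoid response elements of known target genes, which may place them nearest to genes of the glucocorticoid-induced list. Of the list, 6 genes (CXCR4, FKBP5, PER1, SESN1, TSC22D3 and ZBTB16) were nearest to 1 of the 61 gained runs. The count was compared with 10000 draws from 1934 runs of bins chosen by the same recurrence. The mean of the draws was 0.526 genes and the highest 5 (permutation p = 0.0001, one-sided, the smallest these draws can give). The gained bins thus fall near genes of the list more often than bins drawn for the same recurrence. Whether the gained bins hold the receptor's motif was not tested.

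The 2.26 Mb of chromosome 7 without a peak in any knockout library could reflect a deletion of the segment in the knockout cells or a loss of the mark over AUTS2 and GALNT17. These cannot be told apart here because the peak lists hold no reads from regions without peaks. A background read count over the stretch would decide it.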
